A study of Arthrobacter sp. CGMCC 3584 with 8 samples.

How the data were processed

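Total RNA of 8 cultures was labelled with a one-colour kit and hybridised to Agilent arrays, 1 array per sample, per the labels' protocols. The 4 groups, wild strain and arpde knockout at 18 h and at 36 h with 2 replicates each, were taken from the source name of each sample. The deposited scanner files hold spot intensity values written by Agilent Feature Extraction (version 10.7 per the submitters' processing notes), which subtracted background and detrended the signal within each array, per the file headers, with no normalization between arrays. The deposited series matrix holds 1 log2 value per probe and array. How the authors made it is not given in the sources used here. Its columns share nearly one distribution with medians of 4.07 to 4.08 and correlate with the log2 scanner signal at 0.993 to 1.00, from which it was read as quantile normalized log2 signal, uncentred and with higher values brighter. It was used as an alternative.

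From the scanner files, control spots and spots with an outlier mark were left out, log2 of the processed signal was averaged over the spots of a probe, and each array's 75th percentile over all 8263 probes was subtracted. The probes carry 8262 names, and probes of 1 name were averaged. A feature was tested if it was well above background on every array of at least 1 group, which left 4396 features: 3303 predicted ORFs, 664 design-number probes and 429 coordinate-named probes. The number of arrays limits the precision. The median spot-to-spot SD of design-number probes within an array was 0.08 to 0.10 on the log2 scale at 36 h and 0.18 to 0.26 at 18 h, where signals were lower.

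Differences were tested with limma (version 3.58.1, R 4.3.3) in 1 model of all 8 arrays with a mean per group, which left 4 residual degrees of freedom and a prior of 3.93 degrees of freedom, and p-values were adjusted by Benjamini-Hochberg over all features. A feature changed where the adjusted p was below 0.05. The series' own rule was a log ratio of the mutant over the wild strain of at least 1 or at most -1, read as log2. The contrasts were the knockout against the wild strain at each time, the difference of these, and 36 h against 18 h in each strain. The series calls the replicates biological but gives no further detail, so p-values measure the spread between these samples. Features to be named were fixed by rule before the data were examined: since no file pairs IDs with products, the 2 highest and 2 lowest log2 differences per comparison among features that passed the test with at least a 2-fold difference, were well above background on all arrays compared and had no overlap between the groups. For the difference between times the condition on overlap was not applied. Where a group was not well above background on any array, its mean was replaced and the fold is given as a bound. The replacement was, per array, the higher of the probe's own signal and the lowest signal of any probe well above background. All 31 gene lists fixed before the data were examined need product names, so 0 lists could be matched and the tests of gene lists were not run.

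The model was tested on simulated data for 4394 features. With 100 features changed by a log2 difference of 1 and 100 by 2, it recovered 13% and 87% for the knockout at 18 h and 12% and 83% at 36 h, and 8.26% and 5.0% of the calls were false. The simulated errors were independent, with 1 variance per feature shared by all groups, as the model assumes. In the data the SD of the replicate difference was 0.90 in the knockout at 18 h and 0.37 in the wild strain at 18 h. These rates may therefore not hold for these arrays, least of all at 18 h. Alternatives were normexp background correction (offset 50), other normalizations, the series matrix, other filters and thresholds, other priors, array weights, the fit to the compared groups alone, the replicate number as a block and leaving out each array. Slide as a block adds nothing to the comparison of the strains, which lies within a slide, and could not be fitted for the times. Neighbour correlations used the 3221 gismo ORFs with a probe sequence of their own in order of ORF number and 100000 permutations of that order (two-sided, Python 3.11.15, numpy 2.4.6). Figures were drawn with matplotlib 3.10.9.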

Results

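The series measured transcript levels in a wild strain of the actinobacterium Arthrobacter, grown in a medium with glucose, urea and hypoxanthine, and in a mutant of it in which arpde was knocked out. The series title calls it a pde gene, the usual short name for a phosphodiesterase, the class of enzyme that hydrolyses cyclic AMP. Cells of both strains were taken at 18 h, labelled as logarithmic phase, and at 36 h, labelled as stable phase. Each of the 4 groups held 2 samples, described by the series as biological replicates, and each sample was hybridised to 1 one-colour Agilent array, so that the small number of arrays limits the precision of every difference below. The arrays carried 8263 probes of 60 bases. Of these, 3381 were named for predicted open reading frames (ORFs), 694 carried only a design number and were spotted 11 times, and 4188 were named by coordinate ranges on 3 other sequence records. The first 2 classes had a mean GC content of 54.4% and 54.0% and are called strain probes here. The coordinate-named class had a mean GC content of 40.7%, and 3280 of its probes were well above background on no array. No file used here pairs a probe with a gene or product name, so features are given by their IDs in the array design, at most 2 higher and 2 lower per comparison. Exceptions are said to have been chosen after their values were seen.

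**Figure D1:**
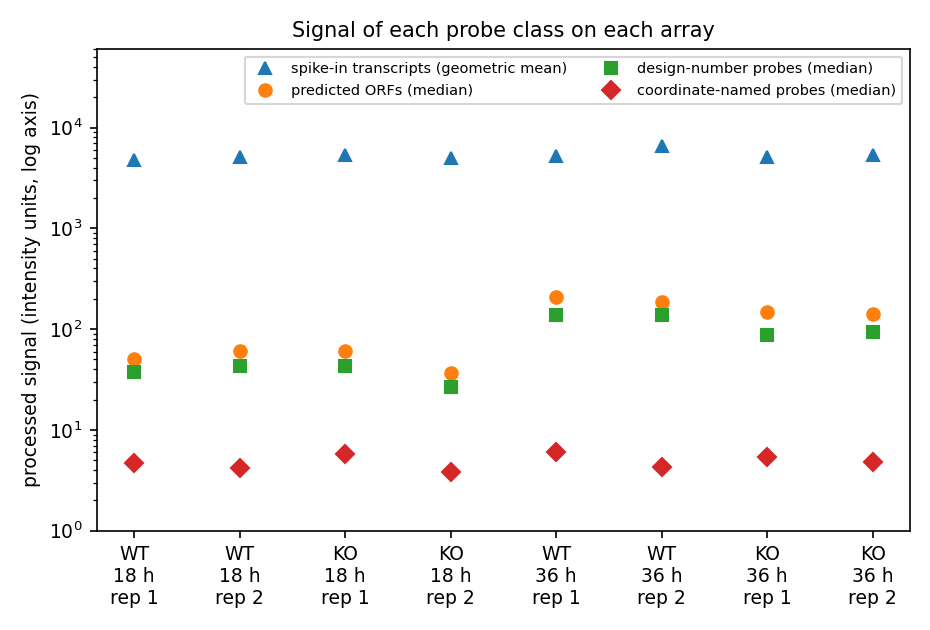
Processed signal (intensity units, log axis) of each of the 8 arrays, grouped by strain, time and replicate along the horizontal axis, with 1 symbol per probe class. The median of predicted ORFs lay between 36.8 and 60.8 at 18 h and between 141 and 208 at 36 h, while the geometric mean of 8 spike-in transcripts lay between 4720 and 6533 on all arrays.

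The median signal of predicted ORFs lay between 36.8 and 60.8 intensity units on the 18 h arrays and between 141 and 208 on the 36 h arrays. Between 84.7% and 99.8% of predicted ORFs were well above background on an array, against 4.18% to 12.8% of coordinate-named probes. No spot was saturated. Across 3965 strain probes the replicates correlated at r = 0.983 for the wild strain at 18 h, 0.954 for the wild strain at 36 h, 0.984 for the knockout at 36 h and 0.881 for the knockout at 18 h. These correlations run across probes, which are not independent replicates. The knockout arrays of 18 h differed from each other by at least 2-fold at 686 strain probes, against 109, 505 and 96 in the wild strain at 18 h, the wild strain at 36 h and the knockout at 36 h. The SD of the log2 difference between replicates was 0.90 in the knockout at 18 h and 0.37, 0.67 and 0.38 in the other groups in the same order. All 18 h arrays lay on slide 1 and all 36 h arrays on slide 2, so time and slide cannot be told apart, whereas each comparison of the strains was made within 1 slide. On both slides the wild strain filled row 1 and the knockout row 2, so strain and slide row cannot be told apart either.

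No probe was assigned to arpde here, so its level is not given. A single predicted ORF, gismo_orf2850, was the sole strain probe well above background on all 4 wild strain arrays and on no knockout array. It was chosen after its values were seen. Its signal lay between 27.5 and 209 intensity units on the wild strain arrays and between 3.6 and 3.78 on the knockout arrays. Taking the lowest signal well above background as the limit on each knockout array, gismo_orf2850 was at least 2.16-fold lower in the knockout at 18 h (limma adjusted p = 0.016) and at least 8.25-fold lower at 36 h (limma adjusted p = 0.00048), in 2 of 2 samples each time. The p-values belong to the fit to the measured signals, which on the knockout arrays lay below that limit. They do not test the bounds. The call at 18 h was lost without any single array other than the knockout arrays of 18 h and in 3 other settings, among them normexp background correction (adjusted p from 0.0024 to 1.00 over its alternatives), and that at 36 h with normexp alone (0.00015 to 0.069).

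The first comparison asked which transcripts differed between the knockout and the wild strain in logarithmic phase. At 18 h, 4 of 4396 features changed, 3 higher and 1 lower in the knockout, all by at least 2-fold. gismo_orf2664 was 32.3-fold higher in the knockout, with a normalised log2 signal of 3.90 ± 0.48 (SD, n = 2) against -1.11 ± 0.25 (SD, n = 2). Its log2 difference was 5.01 with a standard error of 0.36 (limma adjusted p = 0.0035). gismo_orf1981 was 5.85-fold higher, a log2 difference of 2.55 with a standard error of 0.26 (limma adjusted p = 0.016). The other higher feature was a coordinate-named probe and the lower one was gismo_orf2850, described above. gismo_orf2662, named for 36 h below, had a log2 difference of 3.37 at 18 h (limma adjusted p = 0.055) and did not pass. The call of gismo_orf2664 was lost without replicate 1 of the wild strain at 18 h, with normexp and in the fit to these 4 arrays alone (adjusted p from 0.00092 to 0.11 over its alternatives), and that of gismo_orf1981 without any single array other than the knockout arrays of 18 h and in 4 other settings (0.0056 to 0.57). By the series' own rule, a log ratio of at least 1 or at most -1 with no test, 127 features were higher and 314 lower. At 18 h, 628 features had an unadjusted p below 0.05. A fit without 1 array leaves a lone array in its group, whose spread is taken from the other groups. Without a knockout array of 18 h, the group whose replicates differed most gave no estimate of spread. The number changed rested on single arrays: it was 613 (124 higher, 489 lower) without replicate 1 of the knockout at 18 h and 9 without replicate 2, 0 and 1 without replicates 1 and 2 of the wild strain at 18 h, 1 without either knockout array of 36 h, and 2 without either wild strain array of 36 h. Quantile normalisation gave 12 (5 higher, 7 lower), spike-in scaling 2 (1 higher, 1 lower), the 75th percentile over strain probes alone 8 (7 higher, 1 lower), normexp background correction 0 and the fit to these 4 arrays alone 0, where 3 settings with no call had 118 to 482 features with an unadjusted p below 0.05.

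The second comparison asked the same in stable phase. At 36 h, 45 features changed, 20 higher and 25 lower in the knockout, all by at least 2-fold. They comprised 38 predicted ORFs (17 higher, 21 lower), 5 design-number probes (2 higher, 3 lower) and 2 coordinate-named probes. Among the higher ones, gismo_orf2664 was 22.9-fold higher (log2 difference 4.52, standard error 0.36, limma adjusted p = 0.0019) and gismo_orf2662 was 19.6-fold higher (4.29, standard error 0.44, limma adjusted p = 0.0042). gismo_orf1981, named at 18 h, was also higher at 36 h by 3.64 on the log2 scale (limma adjusted p = 0.0017). Among the lower ones, gismo_orf2954 had a log2 signal of -2.03 ± 0.09 (SD, n = 2) in the knockout against 1.55 ± 0.19 (SD, n = 2) in the wild strain, an 11.9-fold difference (limma adjusted p = 0.0018). gismo_orf1757 lay at -0.75 ± 0.14 (SD, n = 2) against 2.12 ± 0.21 (SD, n = 2), a 7.31-fold difference (limma adjusted p = 0.0082). For each of these ORFs 2 of 2 knockout samples lay beyond both wild strain samples. The call of gismo_orf1757 was nonetheless lost without any 1 of the 4 arrays of 36 h and with normexp (adjusted p from 0.0021 to 0.11 over its alternatives), that of gismo_orf2662 without replicate 1 of the knockout or replicate 2 of the wild strain at 36 h and with normexp (0.0018 to 0.085), and that of gismo_orf2954 with normexp alone (0.0005 to 0.10).

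**Figure D2:**
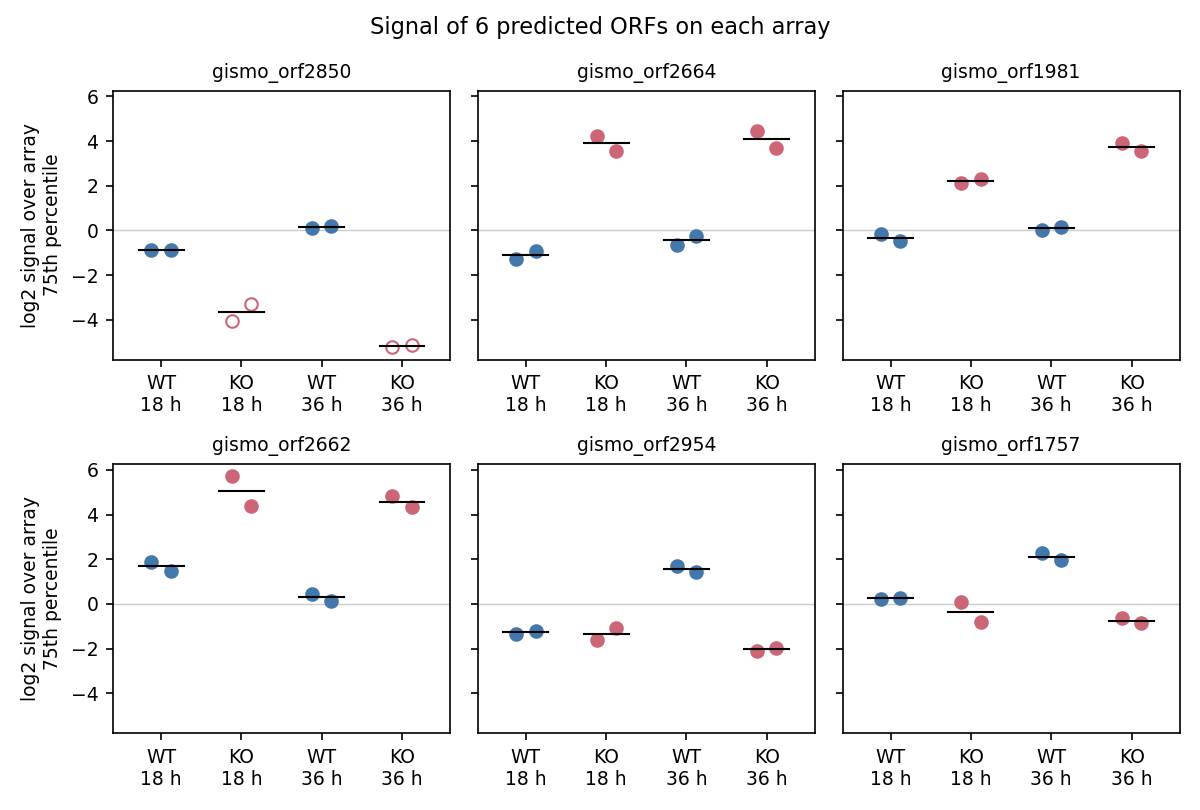
Normalised log2 signal over the array's 75th percentile (vertical axis) of 6 predicted ORFs in the wild strain (WT, blue) and the knockout (KO, red) at 18 h and 36 h. Each circle is 1 array, the bar is the mean of the 2 replicates, open circles mark groups in which neither array was well above background, and gismo_orf2954 stood at 1.55 in the wild strain and -2.03 in the knockout at 36 h.

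The 24 strain probes that were lower at 36 h had a median log2 difference of -2.42, and the 19 that were higher a median of 1.76. Of these 24, 23 rose in the wild strain from 18 h to 36 h, 3 rose in the knockout and 5 fell in it. Of these 19, 13 rose in the knockout and 3 in the wild strain. The wild strain arrays of 36 h enter both differences, and these directions are relative to the 75th percentile of each array. The ratio rule alone counted 243 higher and 175 lower features, and 650 features had an unadjusted p below 0.05. As at 18 h, each fit without 1 array took the spread of its lone array from the other groups. The number changed was 8 and 15 without replicates 1 and 2 of the knockout at 36 h, 12 without replicate 2 of the wild strain at 36 h, 22 without either wild strain array of 18 h, and 115 without either knockout array of 18 h. It was 25 in the fit to the 4 arrays of 36 h alone, 4 with normexp background correction, 20 (4 higher, 16 lower) with spike-in scaling, 30 (7 higher, 23 lower) with quantile normalisation and 42 (11 higher, 31 lower) with the 75th percentile taken over strain probes.

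**Figure D3:**
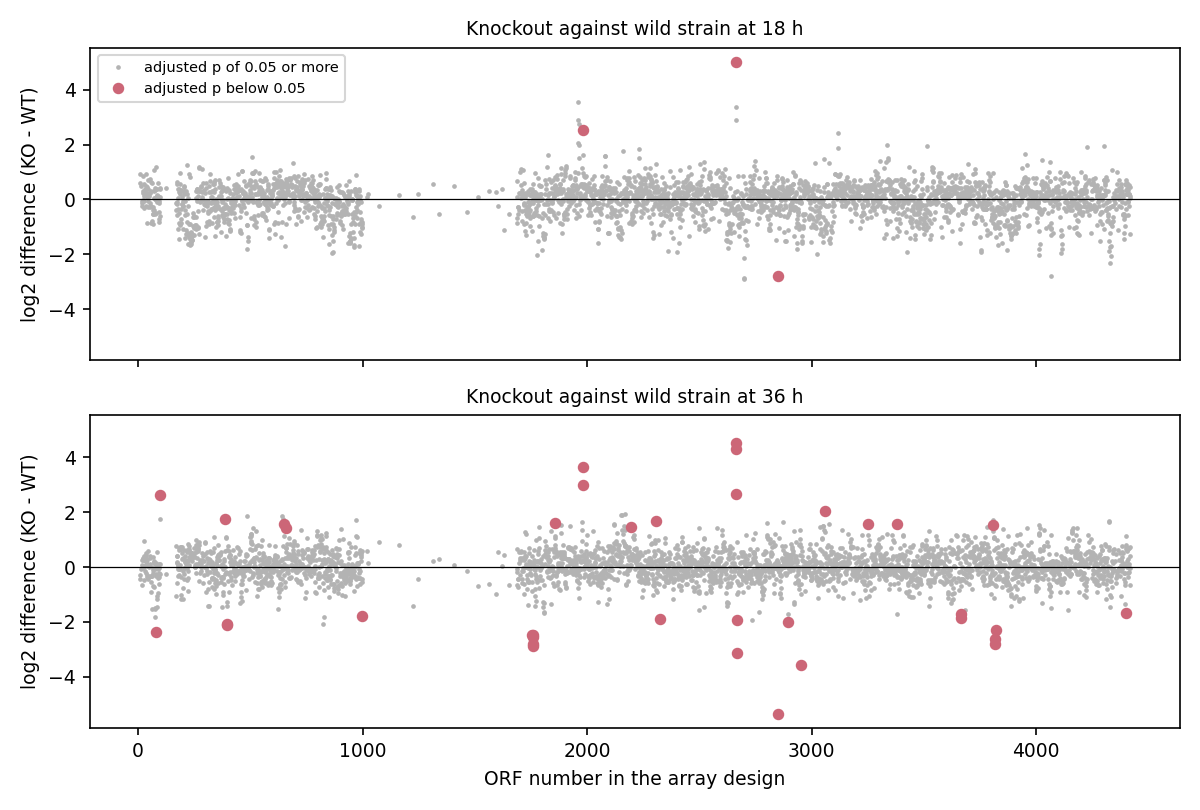
Log2 difference of the knockout from the wild strain (vertical axis) against the ORF number in the array design (horizontal axis) at 18 h (upper) and 36 h (lower), with 1 point per gismo ORF and red points for an adjusted p below 0.05. Several red points at 36 h lie at nearly the same ORF number, among them gismo_orf2662 and gismo_orf2664, which were higher by 4.29 and 4.52.

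The differences between the strains at 18 h and at 36 h were themselves compared. Across 3967 strain probes, the 2 sets of differences, which share no array, correlated weakly (Pearson's r = 0.142, Spearman's rho = 0.116, across probes). Each strain lay in the same slide row at both times, so likeness between these sets cannot be credited to the strain alone. The correlation was 0.275 with quantile normalisation and turned to -0.157 with normexp background correction (rho 0.274 and -0.175). Under the ratio rule, 12 strain probes were higher in the knockout at both times, where independent lists of 96 and 186 would share 4.5, and 35 were lower at both, where lists of 311 and 168 would share 13.2. The difference between the strains changed between the times at 8 features, 2 of them upward and 6 downward. gismo_orf3059 was 1.00 lower in the knockout at 18 h and 2.03 higher at 36 h on the log2 scale, a change of 3.03 with a standard error of 0.35 (limma adjusted p = 0.046). gismo_orf4326 went from -1.89 to 0.73, a change of 2.62 with a standard error of 0.36 (limma adjusted p = 0.04995). gismo_orf2954 went from -0.08 to -3.58, a change of -3.50 (limma adjusted p = 0.046), and CUST_4489_PI428272168 from 0.36 to -2.75, a change of -3.11 (limma adjusted p = 0.046). These 8 calls were not stable, though each fit without 1 array again took the spread of its lone array from the other groups. The count was 403 without replicate 1 of the knockout at 18 h, 1 without replicate 2, and 0 without any other single array, with quantile normalisation, normexp or spike-in scaling, settings in which 256 to 877 features had an unadjusted p below 0.05 against 488 with all arrays.

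Far more features differed between the 18 h and the 36 h arrays than between the strains. Time and slide are the same split, so these changes cannot be credited to growth phase alone. The strains were compared within a slide, though between its rows. In the wild strain 1780 of 4396 features changed from 18 h to 36 h, 740 higher and 1040 lower at 36 h, and 1571 of them by at least 2-fold. Of the 3303 predicted ORFs, 632 rose and 529 fell. Of the 429 coordinate-named probes, 373 fell and none rose, with a median difference of -1.88 that was -0.36 under spike-in scaling. gismo_orf2162 rose 31.6-fold (log2 difference 4.98, standard error 0.53, limma adjusted p = 0.00075) and gm_orf1951 rose 30.9-fold (4.95, standard error 0.56, limma adjusted p = 0.00091). gismo_orf2699 fell by 4.79 on the log2 scale (standard error 0.57, limma adjusted p = 0.0011) and gismo_orf2700, next to it in number, fell by 4.58 (standard error 0.42, limma adjusted p = 0.00061). All 4 kept their direction and passed in each of 25 alternatives, in some of which the log2 difference could not change. The count was 799 without replicate 1 of the wild strain at 18 h and 186 with normexp background correction.

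In the knockout 2212 features changed from 18 h to 36 h, 956 higher and 1256 lower, of which 815 and 692 were predicted ORFs. With normexp background correction the balance turned, to 489 higher and 209 lower. gm_orf1951 rose 17.9-fold (log2 difference 4.17, limma adjusted p = 0.0013) and gismo_orf3006 rose 17.3-fold (4.11, limma adjusted p = 0.00093). Without replicates 1 and 2 of the knockout at 18 h the log2 differences were 3.17 and 5.16 for gm_orf1951 and 3.40 and 4.83 for gismo_orf3006, and both passed in each of 25 alternatives. gismo_orf1960 and gismo_orf2231 had the lowest differences that met the naming rule, -4.17 and -4.11, but these rested on replicate 2 of the knockout at 18 h, where the replicates had an SD of 4.01 and 3.87 on the log2 scale. Without that array the differences were -1.33 and -1.37 (limma adjusted p = 0.014 and 0.023), and without replicate 1 they were -7.01 and -6.85. Both calls were lost without any other single array and with normexp, spike-in scaling, the fit to the groups compared alone, the trended robust prior and loess on probe GC, and that of gismo_orf1960 also with quantile normalisation and the series matrix (adjusted p from 0.00016 to 0.15 over their alternatives). The count was 1256 and 1138 without replicates 1 and 2 of the knockout at 36 h, and 698 with normexp background correction.

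**Figure D4:**
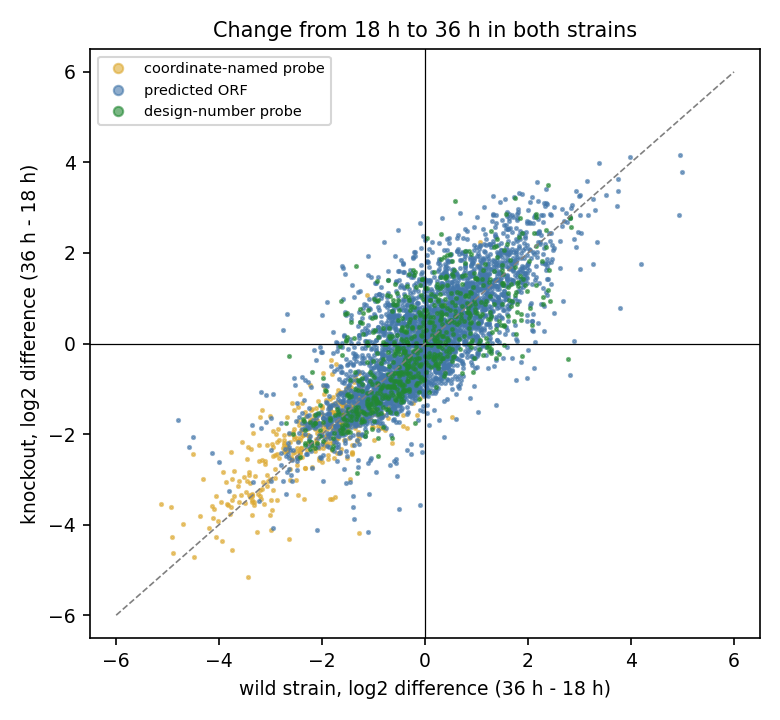
Log2 difference between 36 h and 18 h in the wild strain (horizontal axis) and in the knockout (vertical axis), with 1 point per feature, coloured by probe class, and a dashed line where both are equal. Strain probes follow the line with r = 0.765, and coordinate-named probes lie mostly below 0 in both strains.

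The changes in the 2 strains, which share no array but run between the same 2 slides, correlated at r = 0.765 (Spearman's rho = 0.753, across 3965 strain probes). Of the strain probes, 555 rose in both strains, where independent lists would share 178, and 528 fell in both, where such lists would share 146. Another 12 changed in opposite directions. These directions are relative to the 75th percentile of each array. Scaled instead to the spike-in transcripts, strain probes lay higher at 36 h by a median of 1.46 in the wild strain and 1.49 in the knockout on the log2 scale. The calls then numbered 2522 higher and 130 lower in the wild strain and 2397 higher and 110 lower in the knockout. Quantile normalisation gave 886 higher and 770 lower in the wild strain and 993 higher and 862 lower in the knockout, and the 75th percentile over strain probes gave 638 higher and 1613 lower in the knockout.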

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

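In this part the tests of spot noise, of a wrong time or strain on a label, of a gain common to a slide, of the scaling and of labelling yield, and the spike-in scaling itself, were chosen only after the results were seen; the test of growth stage was set before its result.

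The difference between the strains depended on time at 8 features by the interaction test. The named ones were gismo_orf3059 with a change of 3.03 on the log2 scale and gismo_orf4326 with 2.62, both toward higher signal in the knockout at 36 h, and gismo_orf2954 with -3.50 and CUST_4489_PI428272168 with -3.11, both toward lower signal. The 4 others, chosen here after their values were seen, were gismo_orf1756, gismo_orf1758 and gismo_orf1760, with changes of -2.75, -2.67 and -2.57, and gismo_orf2669. The last was well above background in the wild strain at 36 h alone, so no change is given for it; at 36 h it was at least 7.15-fold lower in the knockout. Without replicate 2 of the knockout at 18 h the count was 1, without replicate 1 it was 403, and without any other single array it was 0.

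The knockout arrays of 18 h differed from each other more than those of any other group, with 48 strain probes at least 8-fold apart, 40 of them higher in replicate 2, against 0 to 2 in the other groups. Spot noise that is independent between ORFs is argued against by the neighbour correlation of the replicate difference, 0.355. An effect of low signal is not excluded by it, because a trend on signal level was not removed. The 75th percentile of signal was 36.9 on replicate 2, against 50.7 to 59.8 on the other 18 h arrays. A wrong time on the label is argued against by the correlations of replicate 2. They were at most 0.762 with a 36 h array and 0.867 to 0.881 with the other 18 h arrays. Another stage between 18 h and 36 h as the main source is argued against: it was to give a correlation of the replicate difference with the wild strain's change above 0.3 in size, and across 3221 gismo ORFs this was 0.0966 with a bootstrap standard error of 0.0357. That the test is judged by the 0.3, and not by a bound of 0.1 also set beforehand, from which the value lies within its error, was decided after the value was seen. A smaller share of such a shift is not excluded. The ORFs named for the wild strain's change all lay further toward their 36 h level in replicate 2 than in replicate 1. These were gm_orf1951 (4.83 against 2.84), gismo_orf2162 (2.90 against 1.36), gismo_orf2699 (0.66 against 1.57) and gismo_orf2700 (2.24 against 2.64). A wrong strain on the label is argued against as well: on replicate 2, the 6 probes that set the strains apart without it lay 2.77 from the wild strain on average (log2), as far as in 1 of 3220 shifts of their spacing along all ORFs, a test that replaced one with a minimum of 10 probes after that one's result was seen; a culture that differed in another way was not tested.

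The median signal of strain probes on an array lay 3.00-fold higher over the spike-ins at 36 h than at 18 h in the wild strain and 2.95-fold higher in the knockout, while the median of the probes' own log2 differences, another measure, was 1.46 and 1.49. A gain common to every spot of the second slide is argued against, because the spike-ins themselves changed by at most 0.242 on the log2 scale between the slides, against 1.83 and 1.59 for the median strain probe. The fall of coordinate-named probes at 36 h, a median of -1.88 in the wild strain and -1.87 in the knockout, may be a product of the percentile scaling, since with spike-in scaling their medians were -0.358 and -0.408. Labelling yield or RNA input that differed between the slides and a biological change in the amount of these transcripts cannot be told apart, because slide and time are the same split and either would give a rise in both strains, as in the array medians, whose rise in the knockout was 1.56 on the log2 scale.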

How the results depend on the processing

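Chosen only after the data were seen were spike-in scaling, leaving out coordinate-named probes, the 75th percentile over strain probes, and loess on probe GC. Counts compare only the size of the lists. Each probe on its own and the probe of highest mean signal repeat the main fit. Spike-in scaling over time gave 2652 calls in the wild strain and 2507 in the knockout. Yet 453 of the 1780 and 561 of the 2212 features called in the main fit then had a log2 difference of opposite sign. Of 139 alternative counts, 79, these among them, stayed within 1.5 times the count reported. For the knockout at 18 h (4), the others were 8 with the 75th percentile over strain probes or over probes detected on all arrays, 1 at an adjusted p below 0.01, 1 with no filter, 0 with normexp, 2 with probes well above background on all arrays only, 0 with only the groups compared, 12 with quantile normalization, 11 with the series matrix, 441 by the ratio rule, 9 with the replicate block and 2 with spike-in scaling. At 36 h (45) they were 17 at the stricter threshold, 25 with no filter, 4 with normexp, 25 with only the groups compared, 418 by the ratio rule and 20 with spike-in scaling. For the difference between times (8) they were 792 by the ratio rule, 5 with a trended robust prior, and 0 at the stricter threshold and with array weights, no filter, normexp, quantile normalization, the series matrix, the replicate block or spike-in scaling. For 36 h against 18 h they were 1020, 4413 and 186 in the wild strain (1780) and 1288, 4668 and 698 in the knockout (2212) at the stricter threshold, with no filter and with normexp. Leaving out 1 array gave 0 to 613 at 18 h, 8 to 115 at 36 h, 0 to 403 for the difference, 799 to 2139 over time in the wild strain and 1138 to 2389 in the knockout; the lone array left in a group was assumed to vary like the other groups. The correlation of the strain differences at 18 h and 36 h was reversed with normexp, -0.157 against 0.142. Normexp with its offset of 50, close to the median ORF signal at 18 h, compresses dim probes by construction; the causes of the other changes were not tested. Of 494 alternative values of the named features and gismo_orf2850, 376 kept direction and call, 118 kept direction and lost the call, and 0 changed direction. In alternatives that alter only the estimate of spread, the filter or an array outside the comparison, the log2 difference is that of the main fit by construction. The direction kept in those is no separate support. Against the scaling reported, the median strain probe shifted by 0.22 at 18 h, -0.14 at 36 h, -0.37 for their difference and -0.37 over time in the knockout with the 75th percentile over strain probes. With that over detected probes it shifted by 0.25, -0.14, -0.38 and -0.24 in the same order and by 0.15 over time in the wild strain. Over time in the wild strain and the knockout the shifts were 0.22 and 0.22 with quantile normalization, 0.23 and 0.23 with the series matrix and 1.52 and 1.47 with spike-in scaling, which gave -0.28 and -0.33 between the strains at 18 h and 36 h, and normexp gave -0.13 over time in the knockout. Replicate numbers, which are also the slide columns, were taken as names that pair no samples, since the labels give no shared source and not every pair of groups had replicate deviations that correlated above 0.1: -0.118 to 0.236 across strain probes, and the replicate block gave 9, 30, 0, 1744 and 2195 calls in the 5 comparisons in the order above. Slide as a block and the tests of gene lists were not run, and the difference between times needs all groups.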

Other observations

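In this part the tests of gene order and of the deleted gene were chosen only after the results were seen; those of spot distance, of probe GC and of a general tendency were set before their results, and the blocks, the clusters and the other groupings of arrays were chosen after the data were seen.

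Part of the ORFs that differed between the strains at 36 h lay side by side in the numbering of ORFs. Of 37 gismo ORFs called at 36 h, 19 had another one called in the same direction within 3 places, against a mean of 1.21 and a highest of 11 in 100000 shuffled orders (permutation p = 1e-05, the smallest these can give). The block of 5 ORFs that holds gismo_orf2662 and gismo_orf2664 was higher in the knockout by a mean of 2.16 at 18 h and 2.30 at 36 h on the log2 scale, with a standard error of 0.28 (limma adjusted p = 0.018 and 0.0036 over 644 blocks). It was the 1 block called at 18 h, where up to 7 were called in 100 shuffled orders, while 21 were called at 36 h, 10 higher and 11 lower, against at most 18 and a median of 4 in shuffled orders. Within the block, gismo_orf2664 differed by 5.01 at 18 h and 4.52 at 36 h, and gismo_orf2662 by 4.29 at 36 h. These 2 ORFs weigh heavily in the block's means, so its test is no separate support for them. The test does not show that all 5 ORFs were higher.

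Across 3221 gismo ORFs, the difference between the strains correlated between ORFs next to each other in number at 0.399 at 18 h and 0.401 at 36 h, above the highest of 100000 shuffled orders, 0.081 and 0.074 (permutation p = 1e-05 for each, adjusted 1e-05 over 9 differences, the smallest these can give). Nearness on the array is argued against, because over the 91.1% of pairs with spots more than 20 rows or columns apart the lower of the correlations was 0.398. Probe GC is argued against, with 0.393 after the mean of each GC content was removed. A candidate explanation is that the numbers follow gene order and that neighbouring ORFs, such as those of an operon, change together; the correlation of 0.399 is the pattern that prompted it and is no separate support, so it stays open. Replicates of the wild strain at 36 h, the knockout at 36 h and the knockout at 18 h also differed by runs of ORFs (0.256, 0.262 and 0.355, against 0.064 in the wild strain at 18 h), so part of the runs may come from single cultures or arrays and not from the strain. A trend on signal level was not removed. In the wild strain at 36 h the replicate difference followed mean level, with a correlation of -0.503.

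A hypothesis for gismo_orf2850, lost from every knockout array, is that it is the deleted gene or part of it. The 4 nearest ORFs by number differed between the strains by at most 0.721 on the log2 scale, so the loss did not extend to them. Strain probes within 0.5 of its level in the wild strain had a median difference of 0.16 at 18 h and 0.07 at 36 h. The lowest among them were -2.01 and -3.12. These are measured differences, so they are not on one scale with the bounds for gismo_orf2850, at least 1.11 and 3.04 lower. Its own measured means were -0.87 in the wild strain and -3.67 in the knockout at 18 h, and 0.16 and -5.19 at 36 h. Both gaps are wider than the lowest differences above, but its knockout signals lay below the limit of detection. A single probe of this kind is not particular to the split by strain. There are 36 ways to pick 2 arrays of each time. Of these, 5, the wild strain arrays among them, gave at least 1 strain probe detected on all picked arrays and on none of the rest. The highest of the others was 3, and picking the knockout arrays gave 0. Deletion and silencing cannot be told apart from RNA, and no name in the files links this ORF to arpde.

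Strain probes that were lower in the knockout at 36 h were mostly ones that rose in the wild strain: 23 of 24, with a median rise of 1.87 on the log2 scale against -0.10 in the knockout. With spike-in scaling the median strain probe rose by 1.46 and 1.49, so that such ORFs would not be flat in the knockout on that scale. The hypothesis that ORFs rising in the wild strain rise less in the knockout in general, which tests all strain probes and not these 24 alone, and whose wording was narrowed to a general tendency after its result was seen, was not borne out. With no array shared, the difference between the strains at 36 h and the wild strain's change correlated at -0.0966 in one split of the wild strain arrays of 36 h and at 0.0403 in the other. With all arrays the covariance was -0.129, against -0.0974 simulated with no effect. The simulation gave all groups the spread averaged over the 4 groups. Only the wild strain arrays of 36 h enter both differences, with an SD of the replicate difference of 0.67. The knockout at 18 h, with 0.90, enters neither, so no conclusion is drawn from the gap between the covariances. Replicate 2 of the wild strain at 36 h was higher than replicate 1 at dim probes and lower at bright ones (correlation of the replicate difference with mean level -0.503, against -0.156 to 0.0986 in the other groups).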
